A study of Mus musculus with 18 samples.

How the data were processed

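Total RNA from 10 samples was measured on 18 single-colour oligonucleotide arrays of 2 mouse platforms. The UniSet Mouse 20K I product, called the 12-array platform here, carried ESC replicate 1, 3-day EB replicates 1 and 2 and 7-day EB replicates 1 and 2 on 2 arrays each, and adult tissue replicates 1 and 2 on 1 array each. The Mouse Whole Genome product, called the 6-array platform, carried ESC replicate 2, 3-day EB replicate 3 and 7-day EB replicate 3 on 2 arrays each. Per the labels' protocols, RNA was treated with DNase, amplified linearly with biotin-labelled nucleotides and read with Cy5. Arrays sharing a group and the first number of their title were treated as 1 sample, a reading that the labels do not spell out.

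Each array came with a scanner export. Its raw column holds 1 intensity per spot, written by scanner software 4.1.0.29054 per the file headers. The headers do not name a background step, but the column has values below 0, so background had already been subtracted. A further column holds the intensity after the authors' median normalization per array (spot based and trimmed, per the file headers). The deposited matrix of the whole series and the deposited value table of each platform hold median-normalized intensities. For the 6-array platform, the matrix holds them beside other probes' names, and the value table does not match the exports by probe. For the adult arrays both hold other values than the exports. Every main value therefore comes from the scanner exports. The normexp background step planned for separate spot and background columns was not applied because the background had already been subtracted.

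Spots marked as masked, contaminated or irregular were set aside, the other spots of a probe were averaged, and values were quantile-normalized within each platform. Values then under the median normalized negative control (3.56 on the 12-array platform, 5.52 on the 6-array platform) were raised to it. Values were put on the log2 scale, and the arrays of a sample were averaged (avearrays in limma). Of the 19758 gene probes shared by the 18 arrays, 15803 carried 1 gene symbol through sequence accessions, the platform table or the probe description, which together covered 14334 genes. Unnamed probes stayed in the tests as they are. Another 3907 probes had no symbol and 48 matched several genes. Probes were kept when above background, by the scanner's marks, on every array of at least 1 group in the fit, and the probe with the highest mean stood for its gene. This left 6302 genes (5685 of them named) for the EB comparisons and 10084 (8873 named) for the adult comparison.

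Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment over the genes tested, adjusted p under 0.05). The EB fit used 8 samples with the platform as a term, with 4 residual degrees of freedom and a prior worth 3.97. The adult fit used the 12-array platform, with 1 ESC sample against 2 adult samples, and the EB samples in the fit supplied much of the spread, so the lone ESC sample is assumed to vary like the others. It had 3 residual degrees of freedom and a prior worth 4.19. These p-values measure the spread between these samples only, because the labels do not say whether replicates were separate cultures. The number of arrays limits the precision.

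The 33 gene lists hold 637 genes, of which 17 had no named probe. They cover pluripotency and epiblast states, germ layers and early lineages, signalling targets, metabolism, cell cycle, stress, feeder fibroblasts and 6 adult tissues. Lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry beside it. No camera call in any comparison held with an estimated correlation. Member counts are also given adjusted over the list alone. The comparisons, filters, lists, rule for named genes and first set of alternatives were chosen before the data were examined.

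Named genes follow a rule set in advance: the 8 largest rises and falls past the threshold that went the same way on both platforms where both were used, up to 3 members with the smallest p from each list with called members, and a fixed set of lineage genes. The text leaves out some of the genes that the rule names, from each of its parts. Genes outside the rule are said to be so where they appear. For a gene below background on every array of 1 group, the fold is a lower bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest above-background signal and the probe's own signal. Medians of lists are given also with such genes at their bound where that changes the value.

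The fits were tested on simulated data built from these samples' spread, with 100 genes changed by a log2 of 1 and 100 by 2. At a log2 of 2, 95% of changed genes were called for 7-day EB against ESC, 100% for 3-day EB against ESC, 99% for 7-day against 3-day EB and 68% for ESC against adult tissue. At a log2 of 1 the shares were 46%, 47%, 71% and 5%. Of the calls, 2.8%, 6.4%, 6.6% and 12% were false, in the same order. The simulated noise was independent between genes and drawn from the variances after eBayes shrinkage, so power on the real data may be lower. Between 7-day and 3-day EB, genes with fitted differences beyond a log2 of 2 did not pass in the real data. A difference of that size that did not pass is therefore not shown to be absent.

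Alternatives covered the authors' normalized values, another floor, median centring, no filter and a filter on every array, every probe, each array as a sample, duplicateCorrelation, leaving out each replicate, a replicate block, scan batch as a block, each platform alone, trend and robust eBayes, and a stricter threshold. Chosen after seeing the data were normexp with the negative controls, scaling on probes above background on every array, quantile normalization without the adult arrays, leaving out the array with the most irregular spots, the deposited tables with their probe names as given, scan batch as a block for the gene lists, the alternatives of the overlap, and the overlap with no ESC sample in common. Probes found only on the 6-array platform were left out of the tests because each group has 1 sample on it. Probes that met the filter only on that platform were left out too. Reading and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.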

Results

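Mouse embryonic stem cells (ESC) of the line MES3, grown on feeder fibroblasts with the cytokine LIF, were profiled beside embryoid bodies (EB), the floating aggregates that form when pieces of ESC colonies are cultured on low-adhesion plates without LIF. There were 2 ESC samples, 3 samples of EB after 3 days and 3 after 7 days, together with 2 samples of adult tissue RNA. On the 12-array platform, 27.7 to 36.2% of gene probes lay above background on the ESC and EB arrays and 52.6 to 57.9% on the adult arrays. On the 6-array platform the share was 60.3 to 71.7%. The median intensity was 2.06 to 3.09 times the median negative control on the 12-array ESC and EB arrays, 7.27 to 10.9 times on the adult arrays and 6.66 to 12.9 times on the 6-array platform.

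**Figure D1:**
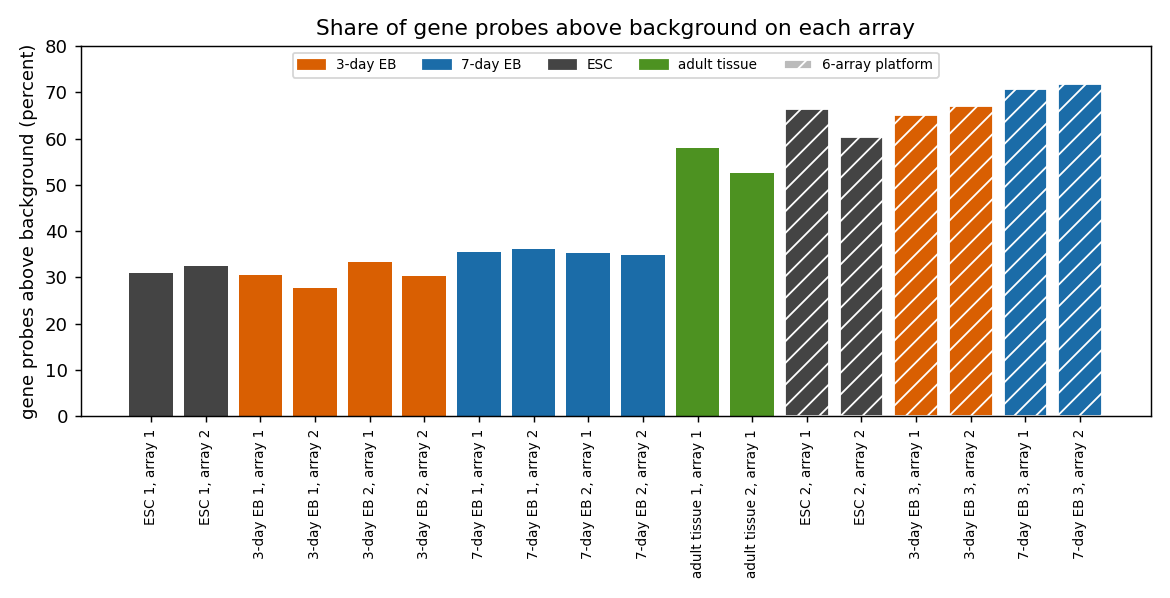
Share of gene probes above background, in percent, on each of the 18 arrays, coloured by group and hatched for the 6-array platform. The ESC and EB arrays of the 12-array platform sit between 27.7 and 36.2%, and all other arrays lie higher.

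Across genes, arrays of 1 sample correlated at 0.958 to 0.977 on the 12-array platform, and arrays of different samples of 1 group at 0.941 to 0.966. ESC against EB arrays gave 0.913 to 0.941, EB arrays of different days 0.934 to 0.959, and adult against ESC or EB arrays 0.423 to 0.492. On the 6-array platform ESC against EB arrays gave 0.868 to 0.923 and EB arrays of different days 0.934 to 0.940. Genes are not independent replicates, so these correlations describe the arrays only. After each platform's mean was taken out, the first principal component held 47.7% of the variance and placed both ESC samples (36.5 and 41.1) apart from the 6 EB samples (-20.7 to 4.9). The second held 22.3%, with 7-day EB replicates 1 and 3 at 24 and 23.8 but 7-day replicate 2 at -3.9. On it the 3-day samples lay at -14, -11.8 and -24 and the ESC samples at 5.7 and 0.2.

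After 7 days in EB culture, the endoderm and trophectoderm lists lay above ESC and the feeder fibroblast list below, by camera with a preset correlation and not with an estimated one. Igf2, an imprinted growth factor, rose by a log2 of 5.98 ± 1.03 (SE, limma adjusted p = 0.0207, n = 3 EB and 2 ESC samples), and the homeobox genes Rhox6 and Rhox5 rose by 5.25 ± 0.60 (adjusted p = 0.00458) and 3.24 ± 0.33 (adjusted p = 0.00377). Apoa1 and Fgb, which encode plasma proteins of endoderm and liver, rose by 4.86 ± 0.80 (adjusted p = 0.0175) and 4.61 ± 0.75 (adjusted p = 0.0164). Id2, a target of BMP signalling, rose by 3.97 ± 0.49 (adjusted p = 0.00581). In ESC replicate 1 Igf2, Rhox6, Apoa1, Fgb and Id2 lay at log2 values of 3.194, 2.265, 2.317, 2.053 and 2.521. These are under the 3.231 of Sox2, which was not above background there, so the sizes of these rises cannot be taken as exact. The comparison asks which genes change once ESC leave the conditions that hold them undifferentiated. Of 6302 genes tested, 325 passed, 113 higher and 212 lower in EB, and 286 of these differed at least 2-fold (95 higher, 191 lower). At an unadjusted p under 0.05 there were 1418 genes, where 315 would come by chance.

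The endoderm list had 12 tested members, of which 3 were higher, none lower and 9 did not pass, and its median was 3.28 (camera adjusted p = 0.000111, adjusted p = 0.635 with an estimated correlation). Adjusted over the list alone, 8 were higher and 1 lower. Besides Apoa1 and Rhox5 the passing member was Cited1, a transcriptional co-regulator (3.33 ± 0.76, adjusted p = 0.0490). Ttr, which encodes the thyroid hormone carrier transthyretin, had the largest difference of the list (5.68 ± 1.37) without passing (adjusted p = 0.056), and Gata4, an endoderm transcription factor, differed by 0.15 (adjusted p = 0.795). In ESC replicate 1 Cited1 (2.88) and Ttr (2.42) also lay under the value of Sox2, so their sizes cannot be taken as exact. The list's median was above ESC in each sample: 3.66 and 1.70 on the 12-array platform and 3.49 on the 6-array platform. The trophectoderm list (7 tested, 2 higher, 5 not passing, 5 higher adjusted over the list alone) had a median of 2.36 (camera adjusted p = 0.00033, adjusted p = 0.393 with an estimated correlation). Its called members were Igf2 and Krt7, a keratin of simple epithelia (2.36 ± 0.28, adjusted p = 0.00547). In the epithelial list 1 of 11 members was higher and 10 did not pass (4 higher adjusted over the list alone). Its median was 0.67 (camera adjusted p = 0.0140, adjusted p = 0.659 with an estimated correlation), and the tight junction gene Cldn7 rose by 1.28 ± 0.25 (adjusted p = 0.0315). Car4, a membrane-bound carbonic anhydrase, completed the 8 largest rises (3.37 ± 0.77, adjusted p = 0.0490).

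The formative and primed epiblast list lay lower: of 5 tested members, from 16 written, 3 were lower and 2 did not pass (4 lower adjusted over the list alone), with a median of -1.40 (camera adjusted p = 0.00033, adjusted p = 0.397 with an estimated correlation). Fgf5, of the fixed lineage genes, stayed outside the tests and lay 0.49 above ESC on the 6-array platform. The feeder fibroblast list had a median of -3.17, and whether feeder RNA adds to the falls of this list was not tested. Dnmt3a, a de novo DNA methyltransferase, fell by 2.33 ± 0.34 (adjusted p = 0.0117), Enpp2, which encodes the secreted enzyme autotaxin, by 1.98 ± 0.26 (adjusted p = 0.00729) and the zinc finger gene Zic2 by 1.40 ± 0.29 (adjusted p = 0.0360). The core pluripotency list did not shift (12 tested, 1 higher, 11 not passing, median -0.40, camera adjusted p = 0.530), nor did the naive pluripotency list (14 tested, none passing, median 0.00, camera adjusted p = 0.785). The medians of the core list were -0.06 and 0.22 on the 12-array platform and -0.66 on the 6-array platform. Pou5f1, which encodes the core factor Oct4, differed by -0.72 ± 0.32 (adjusted p = 0.232), Zfp42 by 0.26 (adjusted p = 0.846) and Klf4 by -0.43 (adjusted p = 0.260). Sox2 differed by 1.27 (adjusted p = 0.101), at 0.45 on the 6-array platform, while ESC were not above background on the 12-array platform, so the pooled value is no exact size. The called member was Sall4, a zinc finger factor of pluripotent cells, which rose by 1.22 ± 0.18 (adjusted p = 0.0125).

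The feeder fibroblast list had the lowest median of the lists tested. In it 11 of 20 tested genes were lower, none was higher and 9 did not pass (14 lower adjusted over the list alone), and the median was -3.17 (camera adjusted p = 6.91e-12, adjusted p = 0.393 with an estimated correlation). The collagen VI genes Col6a2 and Col6a3 differed by -4.22 ± 0.38 (adjusted p = 0.00316) and -4.12 ± 0.42 (adjusted p = 0.00377), and Timp3, an inhibitor of matrix proteases, fell by 2.84 ± 0.26 (adjusted p = 0.00316). S100a4, a calcium-binding protein of fibroblasts, fell by 5.87 ± 0.65 (adjusted p = 0.00441) and the matrix gene Thbs2 by 4.49 ± 0.67 (adjusted p = 0.0122). In the 7-day samples of the 12-array platform Thbs2 lay at log2 values of 1.831 and 2.298 and Col6a3 at 2.812 and 2.404. Both are dim there, so their sizes cannot be taken as exact. Col3a1, a fibrillar collagen, differed by -2.86 ± 1.74 and did not pass (adjusted p = 0.368), at -4.36 on the 12-array platform and -0.44 on the 6-array platform. On the 12-array platform it lay at 9.003 in ESC replicate 1, 7.309 in 7-day replicate 1 and 1.978 in 7-day replicate 2. The -4.36 thus averages unlike samples. Tm4sf1, Ltbp2, Apbb1ip and Cox7a2, outside the feeder list whose median was -3.17, were also among the 8 largest falls, at -6.11 to -4.22. In 7-day EB replicate 1 Tm4sf1, Ltbp2 and Apbb1ip lay at log2 values of 3.186, 2.721 and 2.906, so their sizes cannot be taken as exact. Dkk2, a modulator of Wnt signalling, was at least 13.9-fold lower (fitted log2 -5.50 ± 0.54, adjusted p = 0.0034), being below background on every 7-day array, so its place among the largest falls is not known.

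Other lists held at most 2 calls each, and those with at least 5 tested members did not shift by camera. Kit, the receptor for stem cell factor, rose by 2.06 ± 0.20 (adjusted p = 0.0033) in the germline list (7 tested, 1 higher, 1 lower, median -0.18). Dusp6 and Spry2, feedback inhibitors of FGF and ERK signalling, fell by 1.36 (adjusted p = 0.0129) and 1.29 (adjusted p = 0.0230) among 4 tested members (median -0.63), too few for the list test. In the neuroectoderm list (5 tested, median 0.00) Stmn2 rose by 1.18 (adjusted p = 0.0169) and Pax3 fell by 1.30 (adjusted p = 0.0297). Myl7, an atrial myosin light chain, rose by 1.49 (adjusted p = 0.0338) in the cardiac list (5 tested, median -0.44), and Nid1, of the basement membrane list (11 tested, median 0.51), fell by 1.74 (adjusted p = 0.0318). Hoxb7 fell by 1.54 (adjusted p = 0.0335) in the Hox list (6 tested, median -0.37). That list did not pass with camera (adjusted p = 0.0924) but did with fry (adjusted p = 0.0299), which does not compare it with other genes. The LIF and STAT3 target list (9 tested, 1 lower, median -0.04), the epigenetic regulators (12 tested, 1 lower, median -0.14), the imprinted genes (12 tested, 1 higher, median 0.15) and oxidative phosphorylation (23 tested, 1 lower, median 0.01) did not shift. Cell cycle (26 tested, median 0.13), ribosomal proteins (26, median 0.10), glycolysis and hypoxia (19, median 0.28) and stress response (17, median -0.06) had no called member. Lists with under 5 tested members gave 1 higher of 3 for BMP and TGF-beta targets (Id2), and none of 3 for mesenchymal transition, 2 each for early mesoderm and blood, primitive streak and the 2-cell state, and 1 for Wnt targets. The median and the mean differed in sign for the naive, neuroectoderm and oxidative phosphorylation lists, none of which passed.

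All 325 genes went the same way on both platforms and in all 3 EB samples against the ESC of their platform, as did 48.2% of the genes tested. The genes were called on these same samples, so this agreement is no separate check. Across genes the changes on the platforms correlated at 0.597. The count fell to 86 with scan batch as a term, which takes up the only 7-day sample of the 6-array platform. It was 24 without ESC replicate 2, 98 without ESC replicate 1, 86 without 7-day EB replicate 3, 111 without 7-day EB replicate 1 and 134 without 3-day EB replicate 3. The 12-array platform alone called 1 gene, with 969 at an unadjusted p under 0.05. Median centring gave 68 higher and 211 lower genes, against 113 and 212 here. With each array as a sample the balance turned to 837 higher and 832 lower, and among genes at least 2-fold apart on the 6-array platform alone, with no test, 2837 were higher and 2178 lower.

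**Figure D2:**
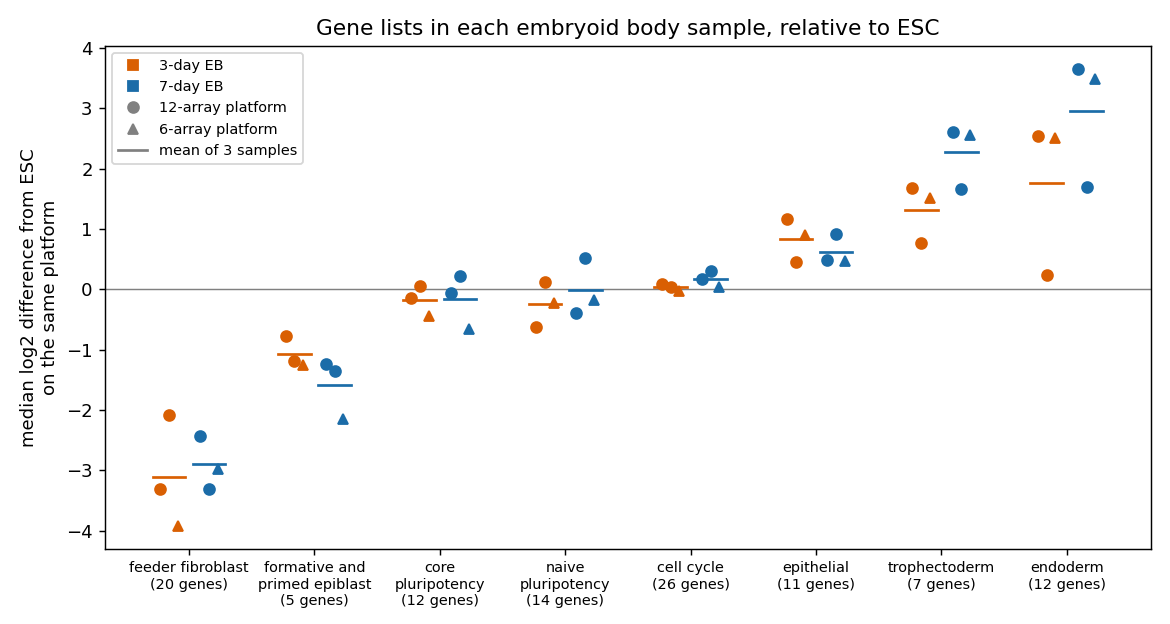
Median log2 difference of 8 gene lists from ESC of the same platform in each of the 3 samples of 3-day (orange) and 7-day (blue) EB, with a line at the mean of the samples. The feeder fibroblast list lies between -3.92 and -2.09 and the endoderm list between 0.24 and 3.66.

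After 3 days in EB culture the feeder fibroblast list again lay below ESC, by camera with a preset correlation and not with an estimated one. Falls outnumbered rises among the genes called, but with each array as a sample 691 were higher and 648 lower, and among genes at least 2-fold apart on the 6-array platform alone, with no test, 2378 were higher and 1969 lower. Fgfbp1, a carrier of fibroblast growth factors, had the largest rise among the genes that passed, 3.54 ± 0.33 (limma adjusted p = 0.00395, n = 3 EB and 2 ESC samples). Id2 rose by 2.43 ± 0.49 (adjusted p = 0.0441), Rhox5 by 2.09 ± 0.33 (adjusted p = 0.0198) and Clu, the chaperone clusterin, by 2.12 ± 0.40 (adjusted p = 0.0366). Rgcc, Wfdc2, Tnni2 and Cd2 completed the 8 largest rises with 1.89 to 2.30. In ESC replicate 1 Fgfbp1 lay at a log2 of 2.765 and Id2 at 2.521, under the 3.231 of Sox2. The sizes of these rises cannot be taken as exact. The comparison shows the early part of the same change of culture. Of the 6302 genes, 178 passed, 41 higher and 137 lower, and 171 differed at least 2-fold (37 higher, 134 lower). At an unadjusted p under 0.05 there were 1203 genes, where 315 would come by chance.

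The feeder fibroblast list had 9 lower genes of 20, none higher and 11 not passing (18 lower and 1 higher adjusted over the list alone). Its median was -3.37, or -2.89 with the genes below background at their bound (camera adjusted p = 2.63e-15, adjusted p = 0.414 with an estimated correlation). S100a4 fell by 4.99 ± 0.65 (adjusted p = 0.0120), Col6a2 by 3.56 (adjusted p = 0.00568) and Timp3 by 2.55 (adjusted p = 0.00568), and Col6a3 was at least 7.02-fold lower. Outside this list, beside its median of -3.37, Dkk2 was at least 10.8-fold lower and Masp1, a protease of the complement system, at least 8.45-fold. Igfbp7, Ltbp2, Apbb1ip and Syndig1 fell by 3.96 to 4.78. In 3-day EB replicate 1 they lay at log2 values of 3.205, 2.765, 2.109 and 2.773, so these sizes cannot be taken as exact. In 3-day EB replicate 2 they lay at 6.422, 5.289, 4.521 and 2.893, against 9.372, 7.839, 7.523 and 6.355 in ESC replicate 1. Igfbp7, Ltbp2 and Apbb1ip thus fell less in replicate 2 than in replicate 1. Col3a1 differed by -5.44 and did not pass (adjusted p = 0.157).

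The epithelial list (11 tested, 1 higher, 10 not passing, 7 higher adjusted over the list alone) had a median of 1.02 (camera adjusted p = 0.00101, adjusted p = 0.436 with an estimated correlation), and Cldn7 rose by 1.28 (adjusted p = 0.0417). The endoderm list (12 tested, 1 higher, 11 not passing, 3 higher and 1 lower adjusted over the list alone) had a median of 2.16 (camera adjusted p = 0.00651, adjusted p = 0.580 with an estimated correlation). That median was 2.54 and 0.24 in the samples of the 12-array platform and 2.50 on the 6-array platform, and the list did not pass on the 12-array platform alone. The trophectoderm list (7 tested, none passing, 4 higher adjusted over the list alone) had a median of 1.33 (camera adjusted p = 0.00403, adjusted p = 0.414 with an estimated correlation). Primed epiblast genes (5 tested, 1 lower, 4 lower adjusted over the list alone) had a median of -0.97 (camera adjusted p = 0.0012, adjusted p = 0.414 with an estimated correlation), with Enpp2 down by a log2 of -2.96 (adjusted p = 0.00395). The epigenetic regulators (12 tested, none passing, 1 lower adjusted over the list alone) had a median of -0.31 (camera adjusted p = 0.00192, adjusted p = 0.414 with an estimated correlation).

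Neither core pluripotency (12 tested, none passing, median -0.24) nor naive pluripotency genes (14 tested, none passing, median -0.27) shifted. Pou5f1 differed by -0.73 (adjusted p = 0.270), Sox2 by -0.42 (adjusted p = 0.580, at -0.58 on the 6-array platform and with neither group above background on the 12-array platform) and Dnmt3b, a de novo DNA methyltransferase, by -0.96 (adjusted p = 0.181). Single calls in lists that did not shift were Kit (1.29, adjusted p = 0.0194), Stmn2 (1.14, adjusted p = 0.0254), the p53 target Ccng1 (1.18, adjusted p = 0.0407), Nid1 (-2.50, adjusted p = 0.0140), Hoxb7 (-1.84, adjusted p = 0.0256) and the imprinted growth regulator Grb10 (-3.19, adjusted p = 0.0307). All 178 genes went the same way on both platforms and in all 3 EB samples against the ESC of their platform, as did 52.5% of the genes tested. They too were called on these same samples, so this is no separate check. Across genes the changes on the platforms correlated at 0.711. With scan batch as a term 112 genes passed. The count was 1 without ESC replicate 2, 75 without ESC replicate 1, 6 without 3-day EB replicate 3, 62 without 3-day EB replicate 1, 113 without 7-day EB replicate 1, 299 without 7-day EB replicate 2 and 112 without 7-day EB replicate 3. The 12-array platform alone called 0 genes with limma, with 603 at an unadjusted p under 0.05.

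The changes at 3 and 7 days overlapped. There were 26 genes higher at both times, where independent lists would share 0.7, and 117 lower at both times, where independent lists would share 4.6, and 0 went opposite ways. In 20 simulations of unchanged groups against the same ESC samples, 0 genes were shared in either direction. Hardly any gene passes in unchanged groups, so this count cannot show how many real calls the shared ESC samples would bring together. The log2 changes correlated at 0.814 across genes against 0.609 in the simulation, with a covariance of 0.406 against 0.052, a difference of 0.354. The same sign was seen for 73.8% of genes, against 70.9% simulated. With no ESC sample in common, the 3-day change on the 12-array platform correlated at 0.501 with the 7-day change on the 6-array platform (covariance 0.285, same sign in 57.9% of genes), and the other way round at 0.572 (covariance 0.38, same sign in 59.6%), a comparison chosen after seeing the data. Without ESC replicate 2 the overlap of 143 genes became 1, without 3-day EB replicate 3 it was 6, and without ESC replicate 1, 3-day EB replicate 1, 7-day EB replicate 1 or 7-day EB replicate 3 it was 69, 55, 76 or 63. Shared genes included Dkk2, S100a4, Apbb1ip and Ltbp2 among the falls and Rhox5, Id2, Kit and Cldn7 among the rises.

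Between 7-day and 3-day EB, the glycolysis, endoderm and imprinted lists were higher at 7 days by camera with a preset correlation, but not with an estimated one (adjusted p = 0.654, 0.749 and 0.654) or by fry, and no single gene passed. The comparison asks what the further days of culture add. limma called 0 of 6302 genes, with 927 at an unadjusted p under 0.05 where 315 would come by chance. The smallest adjusted p was 0.0503, shared by Lims2 (1.91 ± 0.21), the endothelial adhesion gene Pecam1 (2.30 ± 0.28), the integrin gene Itgb5 (1.68 ± 0.22), Fgfbp1 (-2.35 ± 0.29), the hormone precursor gene Trh (-1.76 ± 0.22), Plcd4 (-1.95 ± 0.25) and Dcxr (-1.42 ± 0.17), with n = 3 samples each. These genes lie outside the naming rule and were chosen after their values were seen. Without 7-day EB replicate 2 the count was 174, and without any other 1 sample it was 0. On the second principal component that replicate lay nearer the 3-day samples than the other 7-day samples. A filter on every array gave 3 genes, duplicateCorrelation 182 and scan batch as a term 0.

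The glycolysis and hypoxia list (19 tested, 5 higher and 1 lower adjusted over the list alone) had a median of 0.56 (camera adjusted p = 0.000671, adjusted p = 0.654 with an estimated correlation), with 0.44 on the 12-array and 0.29 on the 6-array platform. The endoderm list (12 tested, 2 higher adjusted over the list alone) had a median of 1.06 (camera adjusted p = 0.00639, adjusted p = 0.749 with an estimated correlation), with 1.37 and 1.11 on the platforms in the same order. The imprinted list (12 tested, none passing adjusted over the list alone) had a median of 0.78 (camera adjusted p = 0.00688, adjusted p = 0.654 with an estimated correlation), with 0.47 and 1.03, and did not pass on the 12-array platform alone. Its median against ESC was -0.25 in 7-day EB replicate 2, within the 3-day samples' range of -0.26 to -0.09. The feeder list did not shift between the days (median -0.25, or 0.00 with genes below background at their bound, mean 0.13, camera adjusted p = 0.830), nor did the core pluripotency list (median 0.01, camera adjusted p = 0.639). Pou5f1 differed by 0.00 (adjusted p = 0.999), Sox2 by 1.69 ± 0.33 (adjusted p = 0.155), at 1.03 on the 6-array platform and with 3-day EB not above background on the 12-array platform, and Ttr by 2.12 (adjusted p = 0.439).

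Against adult tissue, the pluripotency, cell cycle and epigenetic regulator lists were higher in ESC and the adult organ lists lower, by camera with a preset correlation and not with an estimated one. Dppa5a, a gene of pluripotent cells, was at least 342-fold higher in ESC (log2 9.01 ± 0.48, limma adjusted p = 2.65e-05, n = 1 ESC and 2 adult samples). Utf1, a chromatin factor of pluripotent cells, was at least 40.4-fold higher, Mybl2, a cell cycle transcription factor, at least 68.9-fold, and Tdh, which encodes threonine dehydrogenase, differed by 6.58 ± 0.37 (adjusted p = 3.08e-05). In adult tissue the globin genes Hbb-y and Hba-a1 were at least 430-fold and 347-fold higher, though 1 probe may not separate near-identical globins. Scgb1a1, a secreted protein of the airways, was at least 255-fold higher, and the sperm chromatin genes Prm2 and Tnp1 at least 235-fold and 152-fold. The comparison sets the undifferentiated line against adult tissue RNA. The labels name no tissue, leave UNI in the titles unexplained and do not say whether the 2 adult samples are separate RNA or arrays of 1 RNA, so the p-values here may hold only the spread between arrays on the adult side. Of 10084 genes tested, 5262 passed, 2589 higher and 2673 lower in ESC, and 4993 differed at least 2-fold (2405 higher, 2588 lower). At an unadjusted p under 0.05 there were 5940, where 504 would come by chance. Of the lower genes 2025 were below background in ESC, and of the higher genes 225 were below background in adult tissue.

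In the core pluripotency list 9 of 12 genes were higher and 3 did not pass (10 higher adjusted over the list alone), with a median of 3.33, or 2.89 with genes below background at their bound (camera adjusted p = 0.000233, adjusted p = 0.410 with an estimated correlation). Pou5f1 was higher by 5.30 ± 0.48 (adjusted p = 0.000178), Dppa2 at least 23.6-fold, Zfp42 at least 7.76-fold and Sall4 at least 7.53-fold, while Sox2 was below background on every array of both groups. The naive list had 13 of 15 higher, with a median of 3.06 (camera adjusted p = 0.000192, adjusted p = 0.553 with an estimated correlation), although Klf4 did not differ past the threshold (-0.14, adjusted p = 0.714). Cell cycle genes were higher in 24 of 26 cases, with a median of 2.65 (camera adjusted p = 8.53e-09, adjusted p = 0.186 with an estimated correlation), among them the replication helicase genes Mcm5 (at least 35.4-fold), Mcm3 (4.62) and Mcm2 (at least 9.74-fold). Epigenetic regulators were higher in 12 of 13 cases, with a median of 2.58 (camera adjusted p = 5.47e-05, adjusted p = 0.216 with an estimated correlation), including Dnmt3b (5.45), the Polycomb gene Suz12 (3.64) and the histone deacetylase gene Hdac2 (3.30). For these 3 lists the counts adjusted over the list alone were the same 13, 24 and 12.

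Ribosomal protein genes were higher in 18 of 26 cases (median 1.30, camera adjusted p = 9.32e-05, adjusted p = 0.265 with an estimated correlation), among them Rpl3 (3.40) and Rpl27 (3.11). Glycolysis and hypoxia genes were higher in 11 of 20 and lower in 1 (median 1.33, camera adjusted p = 0.000429, adjusted p = 0.410 with an estimated correlation), with Pgk1 at 3.89 and Pfkl at least 14.2-fold higher. Stress response genes were higher in 10 of 17 cases (median 1.30, camera adjusted p = 0.00371, adjusted p = 0.445 with an estimated correlation), including Ccng1 (4.67) and Hmox1, which encodes heme oxygenase (2.70). Basement membrane genes were higher in 6 of 11 cases (median 2.13, camera adjusted p = 0.00486, adjusted p = 0.410 with an estimated correlation), including the nidogen genes Nid2 (4.87) and Nid1 (4.21). Feeder fibroblast genes were higher in 10 of 23 and lower in 1 (median 1.36, camera adjusted p = 0.0370, adjusted p = 0.677 with an estimated correlation), with Ccn1 at 3.60 and Col5a1 at 3.38, while Mgp was at least 29.6-fold lower. Adjusted over the list alone, the higher counts were 18, 12, 10, 7 and 10, with 1 lower in all but the basement membrane list.

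All 8 testis genes were lower in ESC (median -6.56, or -4.66 with genes below background at their bound, camera adjusted p = 1.15e-05, adjusted p = 0.216 with an estimated correlation), among them Smcp, a protein of sperm mitochondria (at least 182-fold). Liver genes were lower in 10 of 11 cases (median -4.38, or -1.87 at the bound, camera adjusted p = 0.000192, adjusted p = 0.216 with an estimated correlation), with Cyp2e1 at least 18.9-fold and Mup1 at least 15.7-fold. Kidney, gut and lung genes were lower in 8 of 10 cases (median -4.61, or -2.52 at the bound, camera adjusted p = 0.000603, adjusted p = 0.410 with an estimated correlation), with the surfactant gene Sftpc at least 92.2-fold. Immune genes were lower in 9 and higher in 2 of 12 (median -2.64, or -1.13 at the bound, camera adjusted p = 0.00371, adjusted p = 0.429 with an estimated correlation), with Cd74 and H2-Aa of antigen presentation at least 5.30-fold and 6.39-fold. Muscle and heart genes were lower in 6 of 9 (median -2.75, or -1.23 at the bound, camera adjusted p = 0.0157, adjusted p = 0.410 with an estimated correlation), with myoglobin, Mb, at least 8.82-fold. Brain genes were lower in 5 of 9 (median -1.97, or 0.00 at the bound, camera adjusted p = 0.0105, adjusted p = 0.315 with an estimated correlation), with the synaptic gene Snap25 at -3.76 ± 0.29 (adjusted p = 9.28e-05). Early mesoderm, blood and endothelium genes were lower in 7 of 13 (median -1.55, or -0.76 at the bound, camera adjusted p = 0.0370, adjusted p = 0.563 with an estimated correlation), and this list did not pass after median centring. Adjusted over the list alone, the lower counts in these 7 lists were 8, 10, 8, 9, 6, 6 and 7.

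**Figure D3:**
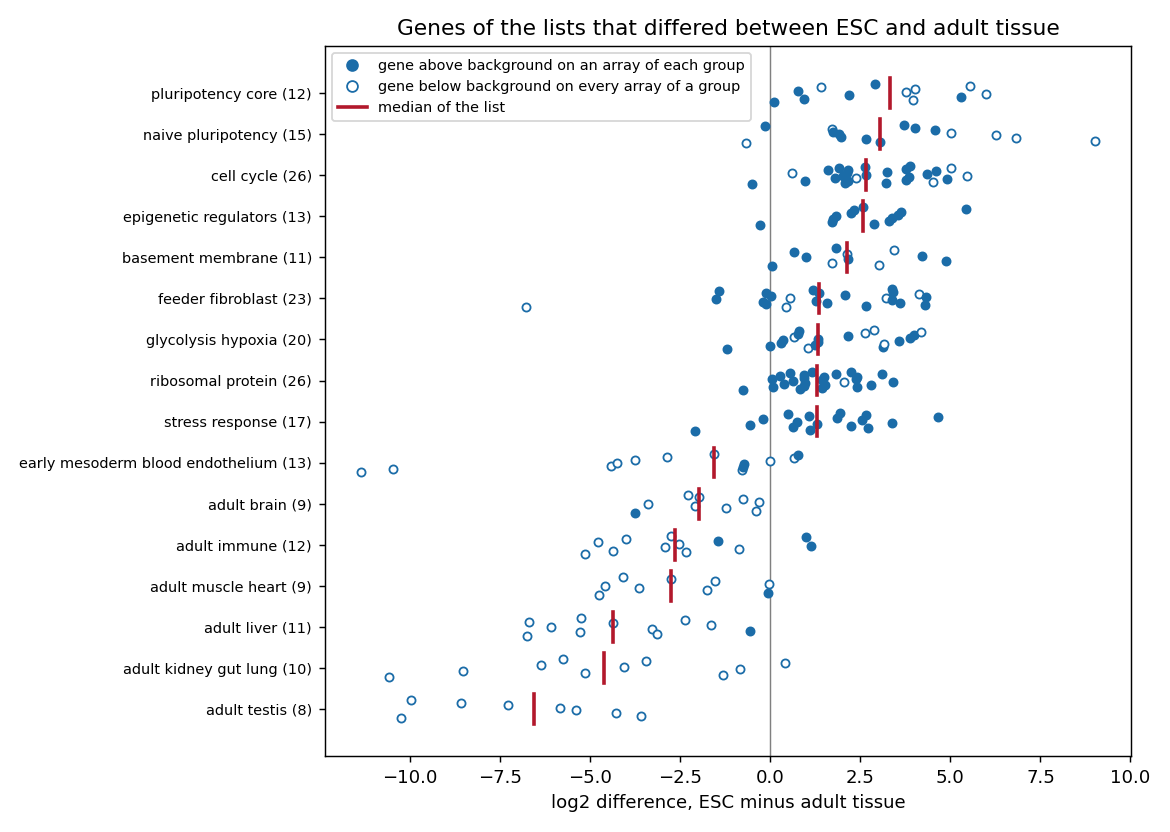
Log2 difference of ESC minus adult tissue for each gene of the 16 lists that passed with camera, with the number of genes in brackets, a red bar at the list's median and open circles for genes below background on every array of a group. The medians run from -6.56 for the testis list to 3.33 for the core pluripotency list.

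Lists that did not shift included endoderm (16 tested, 1 higher, 6 lower), with Ttr at least 24.3-fold and Apoa1 at least 8.05-fold lower in ESC, germline (12 tested, 4 higher, 4 lower), imprinted genes (13 tested, 6 higher, 1 lower), with the placental growth gene Phlda2 at 4.86, epithelial genes (12 tested, 5 higher, 1 lower), with the adhesion gene Cdh1 at 3.95, and oxidative phosphorylation (24 tested, 3 higher, 1 lower). Median and mean differed in sign for the oxidative phosphorylation, Hox and Wnt target lists. The balance of higher and lower genes moved with the scaling: the share of lower calls was 50.8% here, 64.6% after median centring and with the authors' normalized values, 65.6% with scaling on probes above background on every array, 66.7% with the deposited tables and 20% where a gene had to be above background on every array. The median of all genes was 0.05 here, and in the same order -0.35, -0.35, -0.38, -0.39 and 0.70. Without the filter it was 0.17. The adult arrays were scanned in a batch of their own, so the batch and the group cannot be told apart. Leaving out an adult sample gave 4395 or 3988 genes.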

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

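The tests of the left-out genes were chosen only after the results were seen, and the list test between the days was planned. On the 6-array platform 13298 named genes stayed outside the tests, 5110 of them with no probe on the 12-array platform. Because each group has 1 sample on that platform, no difference has a replicate check there. Hbb-y, Hba-x, Igfbp5, Bmp2, Isl1, Hba-a1, Acta1, Gkn2 and Synpo2l, named below, also have a probe on the 12-array platform. They were not kept by the filters over both platforms, and their values on the 12-array platform were not compared. A signal in data outside the comparisons was sought as a gene that lay at least 4 log2 units above ESC on both 7-day arrays, and 23 genes met this, 17 of them with ESC not above background on either array. The 7-day arrays of this platform were scanned in a batch apart from its ESC and 3-day arrays, so day and batch cannot be told apart here. They were chosen by their values. With ESC at the lowest signal above background, the embryonic globin genes Hbb-y and Hba-x were at least 240-fold and 135-fold higher after 7 days, and not above background after 3 days. As in the adult comparison, 1 probe may not separate near-identical globins. The signalling gene Bmp2 was at least 33.0-fold higher, Isl1, a transcription factor of heart and neural progenitors, at least 28.5-fold, and Rarb, a retinoic acid receptor gene, at least 7.21-fold. Among genes above background in ESC, Igfbp5, which binds insulin-like growth factors, lay 6.52 above ESC, the imprinted noncoding RNA H19 4.95 and the adult-type globin gene Hba-a1 4.66. After 3 days 3 genes met the same rule: the skeletal actin gene Acta1 (5.70), Gkn2 (at least 11.3-fold) and Synpo2l (at least 12.5-fold). No explanation was tested for these genes.

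Between 7-day and 3-day EB the change from ESC differed for 3 gene lists by limma camera, with a preset correlation, as a test of the difference itself: glycolysis and hypoxia (median 0.56), endoderm (1.06) and imprinted genes (0.78). The medians of the endoderm list against ESC were 2.54, 0.24 and 2.50 in the 3-day samples and 3.66, 1.70 and 3.49 in the 7-day samples. Those of the glycolysis and hypoxia list were -0.40, -0.05 and -0.25 at 3 days and 0.20, 0.09 and 0.32 at 7 days. Those of the imprinted list were -0.10, -0.09 and -0.26 at 3 days and 0.68, -0.25 and 0.42 at 7 days, so 1 of the 7-day samples lay on the 3-day side. No list passed with an estimated correlation.

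The 6 EB samples split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes, so no split could give fewer, and the highest other gave 1. At an unadjusted p under 0.05 the real split had 927 genes and the highest other 577.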

How the results depend on the processing

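Among the alternatives below, normexp, scaling on probes above background everywhere, quantile normalization without the adult arrays, leaving out the array with the most irregular spots, the deposited tables, the scan block of the gene lists and every alternative of the overlap were chosen after seeing the data. None of the named genes that passed changed direction, but the balance of higher and lower genes turned in places: with each array as a sample it was 837 to 832 at 7 days and 691 to 648 at 3 days, and on the 6-array platform alone 2837 to 2178 and 2378 to 1969, against 113 to 212 and 41 to 137 as reported, and the cause was not tested. Counts are given in the order 7-day EB against ESC, 3-day EB against ESC, 7-day against 3-day EB and the overlap, where the values reported are 325, 178, 0 and 143. Without the filter on dim probes they were 142, 87, 0 and 64, and with a filter on every array, which tests fewer genes, 120, 49, 3 and 35. With each array as a sample they were 1669, 1339, 1020 and 801, and with duplicateCorrelation 747, 522, 182 and 336, since arrays of 1 sample count toward the spread there. Leaving out 1 replicate gave 24 to 478, 1 to 299, 0 to 174 and 1 to 181. Scan batch as a block gave 86, 112, 0 and 63, and the 12-array platform alone, with fewer samples, 1, 0, 0 and 0. The 6-array platform alone, with its own normalization and choice of probes and no test, held 5015, 4347 and 3369 of 22848 genes that differed at least 2-fold, and 99.7% and 99.4% of the reported EB against ESC genes kept their direction there. Its samples are part of the fit that called those genes, so this is no separate check. The deposited tables with their probe names as given, which pair the 6-array platform with other probes, gave 1, 1, 0 and 1. At an adjusted p under 0.01, 63 and 28 genes passed against ESC and 3445 for ESC against adult tissue. The count for 7-day against 3-day EB became 5 with scaling on probes above background everywhere, 6 with quantile normalization without the adult arrays and 7 without the most irregular array, and the cause was not tested. The other alternatives that kept every sample, without a replicate block, gave 279 to 355 and 171 to 217, with the overlap within 136 to 181. Between the days they gave 0 where no count is given above. For ESC against adult tissue a filter on every array gave 2596 genes (2078 higher, 518 lower), since genes dark in a group cannot pass it, and the other alternatives gave 3988 to 6101. The gene lists passing were 5 at 7 days, 6 at 3 days, 3 between the days and 16 against adult tissue. With an estimated correlation 0 passed in each, and with fry 4, 0, 0 and 19. Between the days 7 passed after median centring, 7 with the authors' normalized values and 5 with scan batch as a block, and the cause was not tested. The replicate numbers mark no stated pairing. A replicate block beside the platform gave 162, 72, 12 and 66, with 5195 against adult tissue. The difference between numbers 1 and 2 in 3-day and in 7-day EB correlated at 0.322 across 6316 genes (Spearman 0.313), from a pair of replicates only. The 34, 27 and 102 named genes that passed at 7 days, at 3 days and against adult tissue kept their direction in 827 of 827, 656 of 656 and 1966 of 1966 values and their call in 591, 471 and 1904. Not run were the scan block against adult tissue, where batch and group are the same arrays, and that comparison without ESC replicate 1, its only ESC sample. The dim arrays of the 12-array platform limit what can be tested: their median probe lay 2.06 to 3.09 times above the negative controls.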

Other observations

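Of the tests in this part, those of a single ESC sample, of scaling, of the deposited tables and of the share above background in ESC replicate 2 were chosen only after the results were seen. On the 6-array platform alone, with 1 sample per group and no test, genes of the naming rule that stayed outside the comparisons could be read. The pluripotency genes Nanog and Esrrb lay at 0.25 and -0.12 from ESC after 3 days and at -0.10 and 0.30 after 7 days. Endoderm genes lay higher: Sox17 at 3.27 and 4.07, Foxa2 at 1.93 and 2.80, Gata6 at 1.05 and 2.24, and Afp, which encodes alpha-fetoprotein, at 2.43 and 4.40. The mesoderm genes Kdr and Hand1 lay at -1.48 and 0.55 after 3 days and at 2.56 and 2.13 after 7 days. The primitive streak gene T lay above ESC at both times, at 1.94 after 7 days, and Mixl1, not above background after 3 days, at 1.13 after 7 days. For T, Mixl1, Afp and Cdx2, ESC lay above background on 1 array only, and so did the 7-day sample for Foxa2. The differences of these genes cannot be taken as exact. Cdx2, a trophectoderm and posterior gene, lay at 0.41 and 1.72, Fgf5 at 1.09 and 0.49, and the neural gene Pax6 at -2.61 and -1.89. All these genes but Nanog, Esrrb and Pax6 also have a probe on the 12-array platform, where their values were not compared. The 7-day arrays of the 6-array platform were scanned in a batch apart, so day and batch cannot be told apart here.

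Atf4, the transcription factor of the amino acid response, fell by 1.32 at 7 days and by 1.46 at 3 days. So did Psat1, of serine synthesis (-1.34 and -1.30), Slc7a3, an arginine carrier (-1.74 and -1.82), Atf5 (-2.77 and -3.25) and Stc2 (-1.56 and -1.95). These genes were chosen after their values were seen. A lower activity of the Atf4 programme in EB may link them. A list of 32 known targets without the called genes, written before its values were seen, had 16 tested members with a median of -0.26 at 7 days and -0.63 at 3 days (limma camera adjusted p = 0.022 and 0.000138, 0.43 with an estimated correlation at both times). Between 7-day and 3-day EB its median was 0.30 (camera adjusted p = 0.0439, 0.43 with an estimated correlation). The median at 7 days lay between the bounds set in advance, so the hypothesis stays open.

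Fibroblast genes were lower in EB at both times, and RNA of the feeder cells in the ESC samples is a candidate source, since the ESC were grown on feeders and EB were taken off them. A further list of 40 abundant fibroblast transcripts, holding no gene of the first list and no called gene, had 16 tested members with a median of -1.34 at 7 days and -1.78 at 3 days, both past the bound set in advance (limma camera adjusted p = 0.022 and 3.41e-05, 0.43 with an estimated correlation at both times). A single ESC sample apart from the other is argued against by the first list's medians, of which the one closest to 0 over both platforms and times was -2.57, and the scaling by -2.59 as the closest to 0 over the scalings. Abundant collagen genes did not move alike: on the 6-array platform Col1a1 lay at -3.71 after 3 days but -0.45 after 7 days, and Col3a1 at -6.14 and -0.44, and the further list lay 0.69 higher at 7 than at 3 days (camera adjusted p = 0.00843, 0.43 with an estimated correlation), so expression of matrix genes by EB cells stays open beside feeder RNA. All but 1 of the first list's 20 tested genes lay above background on some 7-day array, which RNA of EB cells or of feeders carried over with the colonies would both give, 3 of its 30 genes are in other lists, and 5 of the 40 further genes are in a fixed list, while a change of the ESC themselves as culture conditions changed was not tested.

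The deposited tables differ from the scanner exports for the 6-array platform and for the adult arrays. In the matrix of the whole series, 100% of values on each of the 6 arrays equal the scanner value at the same place in the order of the 6-array platform, within 0.001, though they stand beside the probe names of the 12-array platform. The 2 arrays of 3-day EB replicate 3 hold each other's values, and the 2 adult arrays of the 12-array platform hold other values (0.47% and 1.55% equal by probe, rank correlations 0.973 and 0.989). For the 6-array platform, another scaling of the same probes is argued against, since over its 6 arrays the highest rank correlation of deposited and scanner values of the same probe was 0.0731. With the probe names as given, limma called 1 gene at each time against ESC, and no biological explanation was tested.

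Among the genes lower in ESC than in adult tissue, 2025 lay below background in ESC replicate 1, whose arrays were dim. Of the 2017 that could be compared, 96.2% were also lower than adult tissue in ESC replicate 2 on the brighter platform, against 61.8% of genes not called and 12.8% of genes higher in ESC. This share lies past the bound set in advance against low signal of the first platform. The genes were picked as high in the same adult samples that serve here, so the share cannot settle that question. On both arrays of ESC replicate 2, 1052 of the 1995 with usable marks, or 52.7%, lay above background, between the bounds, so how many are expressed in ESC stays open. The scan batch of the adult arrays cannot be told apart from the tissue, because 0 scan batches held adult and other arrays. A difference between ESC and tissue, which the design names, is among the open explanations.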
